A study of Mus musculus with 3162 samples.

How the data were processed

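Single cells from mouse glioblastoma were profiled by the submitters in 3 models (EGFR, NF1-PTEN and PDGFR). Per the labels, cells were sorted 1 per well into plates of 96 wells and made into libraries with Smart-seq2 (oligo-dT priming, 22 cycles of PCR) and Nextera XT, and 384 cells were pooled per HiSeq 2500 lane. The gate of the sort is not given in the sources used here, and neither are the aligner, the counting tool and the version of the annotation. The values as deposited are expected counts (estimated counts of reads per gene, not scaled by library), which the authors made against mouse build GRCm38 (mm10). They carry 2 decimals, and 83.6% of the values other than 0 lie within 0.005 of a whole number. The tables have 55541 features, of which 5 are added sequences named Egfrviii, Nf1_Pten, Pdgfra_D842V, iCRE and tdTomato. All 55536 Ensembl IDs were found in GENCODE M21, which gave positions, and 55450 were matched to a gene symbol. The 33 plates gave 3162 labelled wells, 32 of them labelled empty. A further 5 columns belong to no listed sample and were not used. Of 3108 wells compared, 0 pairs held identical values. Each well was kept as 1 cell, and no doublet caller was run because 1 cell was sorted per well.

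Each deposited sample is a cell, so the replicate was taken to be the code in the sample's source name, read as an animal, with 3 codes per model and cells from core and margin for each. If codes are not separate animals, the p-values measure only the spread between these groups of cells. Cells were kept with at least 1000 detected genes, at least 20000 counts and at most 20% mitochondrial counts. They were clustered with scanpy 1.11.5 and leidenalg 0.10.2: log2(CPM + 1), the 2000 most variable genes, animal means subtracted, 30 principal components, 15 neighbours and Leiden resolution 1 with a fixed seed. A cluster took the name of the marker list with most members among its 50 leading genes, with at least 3 members. Of the 26 lists, 13 served for naming: astrocyte, oligodendrocyte precursor, mature oligodendrocyte, neural progenitor and neuroblast, mature neuron, G2/M, reactive injury, interferon response, microglia and macrophage, T and NK cell, endothelial, mural and fibroblast, and ependymal. G1/S and MHC antigen presentation were not among them, so a cluster led by Cdc6, Mcm3 and Ung and one led by Cd74, Ciita and H2-Aa stayed unnamed. Cells in clusters like microglia or macrophages, T or NK cells, endothelium or mural cells did not enter the sums for the gene tests.

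Expected counts were summed per animal and region (18 sums) or per animal (9 sums) and rounded to whole numbers. EdgeR 4.0.16 in R 4.3.3 was used with TMM scaling, filterByExpr, a prior count of 2 and quasi-likelihood F tests, two-sided, with Benjamini-Hochberg adjustment and a threshold of 5%. Core was compared with margin over all models with the animal as a block (8 residual degrees of freedom). A joint fit with a region effect per model (6 residual degrees of freedom) gave the effect in each model and a test on 2 degrees of freedom of whether the effect differs. Models were compared with each other on the 9 sums (6 residual degrees of freedom). Positive log2 values mean higher in core or in the model named first. The SE of a log2 value is its size divided by the square root of the F statistic. Numbers of calls are given as counts or as percentages of the genes tested (19562 between regions, 19563 between models). The pairing follows from core and margin sharing an animal. It was checked on the sums: the deviations of an animal's core and margin from their group means correlated at 0.0879 to 0.281, and in 9 of 9 animals the core lay closest to its own margin.

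The gene lists were tested with limma 3.58.1 by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, adjusted over 26 lists. These were astrocyte, oligodendrocyte precursor, mature oligodendrocyte, neural progenitor and neuroblast, mature neuron, G1/S, G2/M, interferon response, MHC antigen presentation, reactive injury, hypoxia and glycolysis, extracellular matrix, migration and adhesion, immediate-early and stress, cholesterol synthesis, MAPK feedback, glutamate synapse, cytosolic ribosome, mitochondrial genome, microglia and macrophage, T and NK cell, endothelial, mural and fibroblast, ependymal, erythroid, and driver and pathway. The difference in each list's mean log2 CPM was also tested over animals by flipping signs (512 flips, two-sided, smallest p 0.00391 for 9 animals and 0.25 within a model) and between models by all 1680 assignments of the animals. Shares of cells, added sequences and genes per cell were tested in the same exact ways. For groups with 0 counts a floor of 3 counts over the group was used, and a gene with 1 to 3 counts has its level in CPM only. List medians were computed again with members at or under that floor in a group set to it, leaving out those under it in both.

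The lists, the comparisons, most of the tests and alternatives and the rule for naming genes were fixed before the data were examined. The plan did not hold the permutation test of list differences between models or the tests of genes per cell. For core against margin over all models the rule names, per direction, the 10 genes with the largest change among those past the threshold, with a mean of at least 10 CPM and the same direction in at least 8 of 9 animals, leaving out predicted genes. From each list it adds up to 2 called members per direction with a mean of at least 1 CPM, or, where none was called, the 1 or 2 with the highest mean. For the other comparisons it names 5 per direction whose animals do not overlap (10 for the difference between models in the effect of region). Egfr, Pdgfra, Nf1 and Pten are always named, and Xist and Y-linked genes only as a group.

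The alternatives were DESeq2 1.42.0, edgeR with RLE size factors, limma on the mean over cells of log2(CPM + 1), no filter on low counts, no filter on cells, a stricter filter on cells (2000 genes, 50000 counts, 10% mitochondrial), cells thinned to 20000 counts, microglia-like cells kept, no block, and each animal left out in turn. Shares were computed again at resolution 0.5 and 2, without subtracting animal means, under the stricter filter and within plates. Chosen after seeing the data were genes with at least 10 CPM, leaving out S111B1 and S105M3 together, the sign-flip test of lists, clustering without genes called between models, fry for lists between models, resolution and stricter filter for shares between models, and all tests of whether the share difference between core and margin differs between models.

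The procedure was tested on simulated data with the spread of these sums and 200 changed genes. The changed genes were drawn from those with a mean of at least 10 CPM, so the recovery holds for such genes only. Over all models it recovered 47% of genes changed 2-fold and 91% of those changed 4-fold, with 5 false calls among 18098 unchanged genes. In EGFR alone it recovered 6% and 54%, for the difference between models in the effect of region 0% and 34%, and between EGFR and PDGFR 1% and 28%. In the same simulated data as for EGFR against PDGFR, where genes were changed in EGFR only, NF1-PTEN against PDGFR gave 0 calls among 18747 genes. Each gene was drawn independently, so false calls among genes that vary together were not tested. Other tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.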

Results

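Full-length transcript profiles of single cells from mouse glioblastoma were collected from 3 tumour models named EGFR, NF1-PTEN and PDGFR, each with 3 animals. From every animal, cells were taken from the tumour core and from the infiltrative margin, where tumour cells mix with brain tissue. The labels do not state that the code in each sample name is an animal, and it is read so here. Of 3130 labelled wells, 1571 came from core and 1559 from margin, spread over 33 plates that each held both regions of 1 animal. After filtering, 2977 cells remained, 1508 from core and 1469 from margin. The core and margin numbers were 522 and 499 in EGFR, 434 and 427 in NF1-PTEN, and 552 and 543 in PDGFR. The median cell held 352139 estimated counts and 3294 detected genes. Core cells had a median of 356102 counts and margin cells 347451. Summed per animal and region, the counts ranged from 27856571 (NF1-PTEN animal S111B1, margin) to 130210734 (PDGFR animal S105M3, core). Mitochondrial transcripts took a median of 1.48% to 2.71% of a cell's counts. Intervals and floors given here cover counting error only, since reads without molecular identifiers are not independent molecules. The count floor is 3 counts over a group, and where list members lie at or under it in a group, a second median places them there. Values are means ± SD over animals unless an SE is named, and levels are in CPM, counts scaled to a common library total. For the added sequences and for sums with them this is the plain total, and for levels given with a test by edgeR the total after TMM scaling, so levels of the 2 kinds differ somewhat.

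The first question was whether each model carried its own genetic lesion. Egfrviii, a truncated and constitutively active form of the EGF receptor, reached 8547 ± 693 CPM in the 3 EGFR animals and was detected in 99.7% to 100% of their cells. It averaged 0.0269 CPM in NF1-PTEN and 0.521 CPM in PDGFR. Pdgfra_D842V, an activated form of the PDGF receptor alpha, reached 1187 ± 102.9 CPM in the 3 PDGFR animals, in 92.6% to 97.5% of cells. It also took 32.7 ± 20.3 CPM in EGFR and 115.8 ± 160.3 CPM in NF1-PTEN animals. Of the latter, S111B1 held 300.6 CPM, against 32.001 CPM in S93B3 and 14.9 CPM in S93F2. The red fluorescent reporter tdTomato stood at 1316 ± 427 CPM in EGFR, 927 ± 137.7 CPM in NF1-PTEN and 44.8 ± 13.9 CPM in PDGFR. The recombinase iCRE stood at 179.5 ± 63.4, 377.03 ± 252.01 and 55.3 ± 27.4 CPM in the same order. No count fell on the sequence named Nf1_Pten in any animal. That allows up to 0.00783 CPM over the NF1-PTEN animals and 0.00865 CPM over the EGFR animals (3 counts over the group).

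Egfr (ENSMUSG00000020122.16, chromosome 11, 16752203 to 16918158) on build GRCm38, the endogenous EGF receptor gene, was at 0.526 ± 0.912 CPM in EGFR, 35.9 ± 30.4 CPM in NF1-PTEN and 6.76 ± 1.37 CPM in PDGFR animals. No pair of models passed the edgeR test for it (adjusted p = 0.278, 0.314 and 0.615). Pdgfra (ENSMUSG00000029231.15, chromosome 5, 75152292 to 75198215), a receptor of oligodendrocyte precursors, was at 635 ± 268.5 against 116.5 ± 46.5 CPM in EGFR and PDGFR (log2 +2.45, SE 0.50, adjusted p = 0.0374). Of Egfr, Pdgfra, Nf1 and Pten it was the only one that passed in any pair, and reads of this gene and of Pdgfra_D842V can be assigned to either. On plain totals, where Pdgfra stood at 633 ± 288.5 CPM in EGFR, 339.5 ± 205.7 CPM in NF1-PTEN and 107.9 ± 41.8 CPM in PDGFR, the sum of both ran the other way, at 666 ± 308.6, 455 ± 193.97 and 1295 ± 136.5 CPM. The TMM-scaled level of Pdgfra in NF1-PTEN was 313.1 ± 179.9 CPM (adjusted p = 0.389 against EGFR and 0.211 against PDGFR). Nf1 (ENSMUSG00000020716.16, chromosome 11, 79339693 to 79581612), which restrains Ras, stood at 27.2 ± 6.55, 26.996 ± 11.2 and 18.4 ± 2.03 CPM in EGFR, NF1-PTEN and PDGFR (adjusted p = 0.999, 0.413 and 0.533 for the pairs). Pten (ENSMUSG00000013663.7, chromosome 19, 32757497 to 32826160), which opposes PI3-kinase, stood at 18.4 ± 2.98, 10.5 ± 7.60 and 23.4 ± 5.49 CPM (adjusted p = 0.651, 0.831 and 0.443). In NF1-PTEN animals Pten ran from 1.90 CPM in S93F2 to 13.1 CPM in S93B3 and 16.4 CPM in S111B1. Nf1 in the same animals was 15.9 CPM in S93F2, 26.7 CPM in S111B1 and 38.4 CPM in S93B3. Transcripts of both genes were thus still counted in the model named after them. Between core and margin, none of the 4 passed over all models: Egfr (log2 −0.18, SE 1.33, adjusted p = 0.999), Pdgfra (log2 +0.09, SE 0.31, adjusted p = 0.998), Nf1 (log2 +0.47, SE 0.29, adjusted p = 0.837) and Pten (log2 −0.20, SE 0.26, adjusted p = 0.958).

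**Figure D1:**
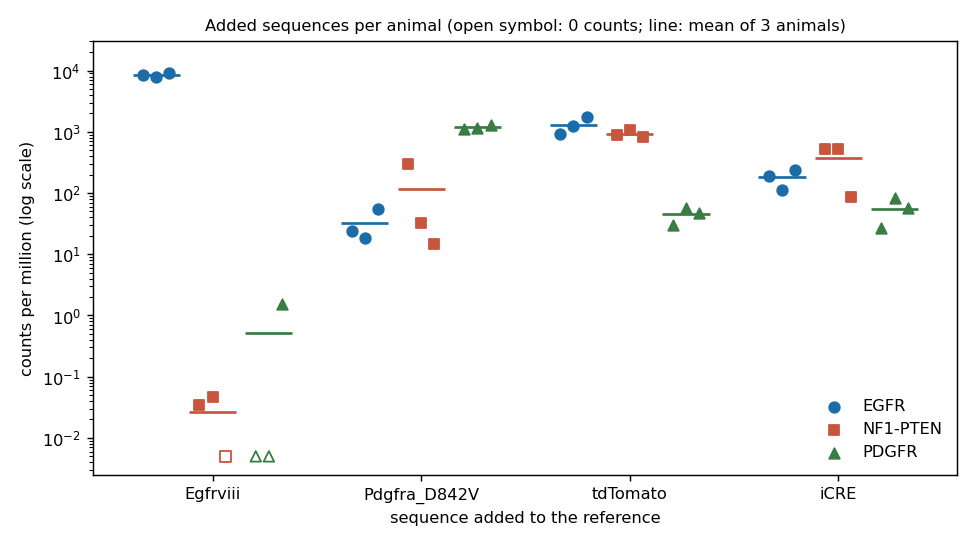
Counts per library total (CPM, log axis) of 4 sequences that were added to the reference, with 1 symbol per animal and a line at the mean of 3 animals per model; an open symbol marks an animal with 0 counts. Egfrviii lies near 8547 CPM in EGFR animals, and Pdgfra_D842V near 1187 CPM in PDGFR animals.

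PDGFR cells held more detected genes than cells of the other models. The median cell of a PDGFR animal held 4996 ± 300.3 genes, against 2793 ± 194.04 in EGFR and 2907 ± 160.9 in NF1-PTEN (3 animals each, exact permutation test over 1680 assignments, p = 0.0179). With every cell thinned to 20000 counts, the medians were 3604 ± 295.4, 2262 ± 240.5 and 2332 ± 151.1 (exact p = 0.0286, adjusted p = 0.0429 over 3 tests of this measure). PDGFR plates ran from 3206 to 3957 genes at equal depth, all above the plates of the other models. The highest of the other plates, EGFR plate P3148, lay 62 genes below the lowest PDGFR plate, at 98.1% of it, while the other 3 plates of its animal held 2224 to 2375. The remaining plates ran from 1863 to 2719.

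**Figure D2:**
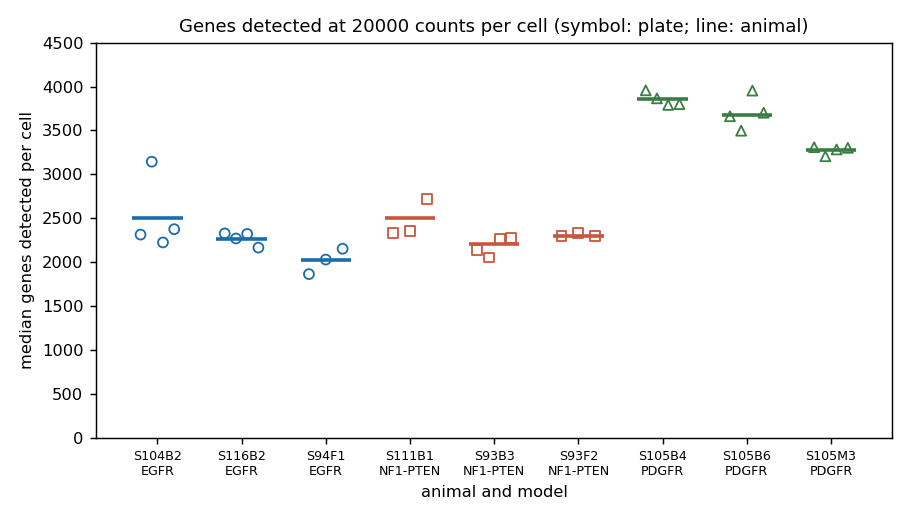
Median number of genes detected per cell at 20000 counts (vertical axis, from 0) for each animal (horizontal axis), with 1 open symbol per plate and a line at the median of the animal. PDGFR animals average 3604 genes, EGFR animals 2262 and NF1-PTEN animals 2332.

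The main question of the study was how cells in the core differ from cells in the margin. Pooled over the animals of all models, cell-cycle and cholesterol synthesis genes were lower in core, while immediate-early and stress genes and MHC antigen presentation genes were higher. All 20 measured G2/M genes, which drive mitosis, lay lower in core (median log2 −0.71, adjusted p = 1.37e-12, adjusted p = 0.348 with an estimated correlation). By model their median was −2.14 in EGFR, +0.02 in NF1-PTEN (adjusted p = 0.817) and −0.33 in PDGFR (adjusted p = 0.0591). Of 20 G1/S genes, which serve DNA replication, 19 lay lower (median log2 −0.32, adjusted p = 5.73e-10, adjusted p = 0.264 with an estimated correlation), with medians of −1.01, +0.05 and −0.28 in the same order of models. All 18 cholesterol synthesis genes lay lower (median log2 −0.51, adjusted p = 1.62e-19, adjusted p = 0.180 with an estimated correlation), with −0.62, −0.18 and −0.74. Of 23 immediate-early and stress genes, 19 lay higher (median log2 +0.51, adjusted p = 4.67e-09, adjusted p = 0.180 with an estimated correlation). Of 18 MHC antigen presentation genes, 16 lay higher (median log2 +0.46, adjusted p = 5.36e-07, adjusted p = 0.356 with an estimated correlation). These first p-values are camera's with its preset correlation, and no list passed with an estimated correlation. With core and margin exchanged in some of the animals, camera with the preset correlation still called 2 to 9 lists in every split drawn. Its p-values alone therefore do not establish a difference between core and margin. Adjusted over the list alone, 10 cholesterol synthesis genes and 5 G1/S genes were lower and 3 immediate-early and stress genes higher, and 0 in the G2/M list. Adjusted over all genes, the count was 0 for each.

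Msmo1, a sterol methyl oxidase, was at 193.7 ± 65.6 against 310.5 ± 98.1 CPM in core and margin (log2 −0.70, SE 0.16, adjusted p = 0.670, lower in 8 of 9 animals). Hmgcs1, which starts the mevalonate pathway, was at 187.5 ± 114.2 against 290.2 ± 147.2 CPM (log2 −0.69, SE 0.21, adjusted p = 0.670, lower in 8 of 9). Mcm6, a subunit of the replicative helicase, was at 244.1 ± 200.7 against 334.96 ± 161.7 CPM (log2 −0.60, SE 0.15, adjusted p = 0.670, lower in 8 of 9). Pcna, the replication clamp, gave log2 −0.19. Ccnb1, the mitotic cyclin, gave log2 −0.82, and Cdc20, an activator of the anaphase-promoting complex, log2 −0.68. Fos, an immediate-early transcription factor, was at 1136 ± 594 against 671 ± 319.2 CPM (log2 +0.76, SE 0.21, adjusted p = 0.670, higher in 9 of 9). The chaperone Hsp90aa1 in the same list gave log2 −0.01. B2m, the light chain of MHC class I, gave log2 +0.44 and H2-D1, a heavy chain, log2 +0.31, each higher in 7 of 9.

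Each animal gave its own estimate of these lists, by the mean log2 CPM of their members. The immediate-early and stress list was higher in core in 9 of 9 animals, by 0.73 ± 0.59 (exact two-sided sign-flip test, p = 0.00391, adjusted p = 0.0508 over 26 lists). That is the smallest p that 9 animals can give. The G1/S list gave −0.44 ± 0.47, lower in 9 of 9 (exact p = 0.00391, adjusted p = 0.0508). The cholesterol list gave −0.53 ± 0.43, lower in 8 of 9 (exact p = 0.00781, adjusted p = 0.0677). The G2/M list gave −0.81 ± 1.37, lower in 6 of 9 (exact p = 0.105, adjusted p = 0.305). The MHC list gave 0.52 ± 0.80, higher in 7 of 9 (exact p = 0.0859, adjusted p = 0.305).

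**Figure D3:**
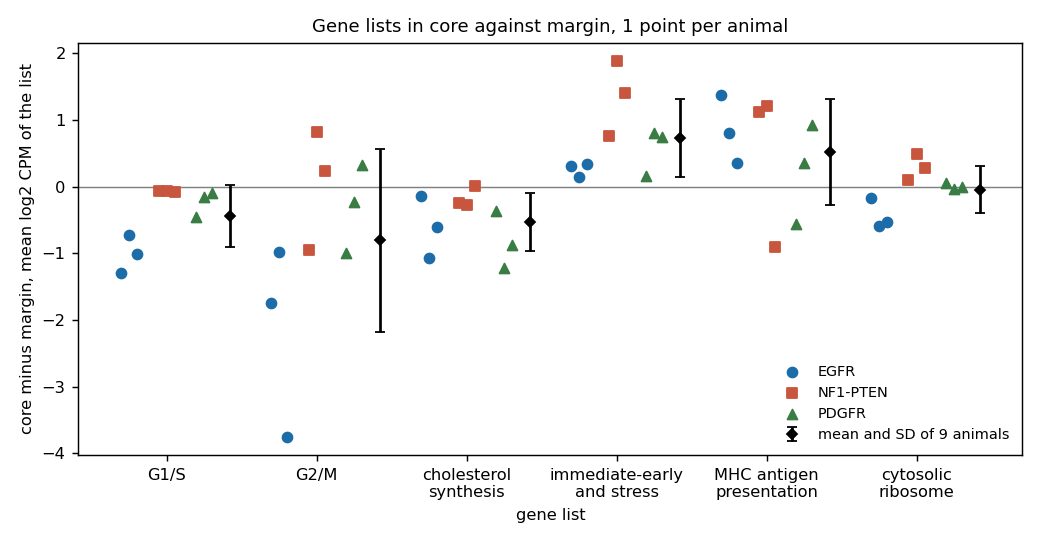
Difference between core and margin in the mean log2 CPM of 6 gene lists (vertical axis, positive is higher in core), with 1 symbol per animal and a diamond with bars at the mean and SD of 9 animals. The immediate-early and stress list lies above 0 in all 9 animals (mean 0.73), and the G1/S list below 0 in all 9 (mean −0.44).

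Markers of other cell types also moved. Of 17 astrocyte genes, 12 lay lower in core (median log2 −0.73, adjusted p = 0.0191, adjusted p = 0.381 with an estimated correlation), although Cst3, a secreted protease inhibitor, gave log2 +0.07 and Aldoc, a glycolytic enzyme, log2 −0.12. Of 8 endothelial genes, 7 lay higher (median log2 +0.97, adjusted p = 0.0191, adjusted p = 0.264 with an estimated correlation). Itm2a gave log2 +0.96, SE 0.28, adjusted p = 0.670 and Ly6c1 log2 +2.18. Of 15 microglia and macrophage genes, 11 lay higher (median log2 +0.52, adjusted p = 0.0297, adjusted p = 0.348 with an estimated correlation). The lysosomal enzyme Hexb gave log2 +0.44 and the microglial receptor P2ry12 log2 +0.86. Of 20 reactive injury genes, 15 lay higher (median log2 +0.35, adjusted p = 0.0454, adjusted p = 0.348 with an estimated correlation). Lgals1, a galectin, gave log2 +0.20 and the intermediate filament Vim log2 −0.52. Without S111B1 or S105B4 the astrocyte call ended (adjusted p = 0.494 and 0.126), and with microglia-like cells kept the microglia list turned lower and its call ended (adjusted p = 0.166). The other calls ended without these animals: endothelial without S105B6, S93B3, S93F2 or S94F1 (adjusted p = 0.112, 0.168, 0.132 and 0.0527), microglia without S105B6, S105M3 or S94F1 (0.152, 0.108 and 0.0527), and reactive injury without any animal but S93F2 (0.0527 to 0.227).

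The other 17 lists did not pass over all models. They were oligodendrocyte precursor (log2 +0.08, adjusted p = 0.323), mature oligodendrocyte (log2 +0.04, adjusted p = 0.295), neural progenitor and neuroblast (log2 +0.12, adjusted p = 0.226) and mature neuron (log2 +0.02, adjusted p = 0.677). Signalling and stress lists were interferon response (log2 +0.04, adjusted p = 0.637), hypoxia and glycolysis (log2 −0.01, adjusted p = 0.992) and MAPK feedback (log2 +0.10, adjusted p = 0.295). Lists of contact with the surroundings were extracellular matrix (log2 +0.62, adjusted p = 0.295), migration and adhesion (log2 −0.03, adjusted p = 0.885) and glutamate synapse (log2 +0.14, adjusted p = 0.992). Housekeeping lists were cytosolic ribosome (log2 −0.04, adjusted p = 0.295) and mitochondrial genome (log2 +0.03, adjusted p = 0.560). Further cell types were T and NK cell (log2 +0.97, adjusted p = 0.295), mural and fibroblast (log2 +0.43, adjusted p = 0.323), ependymal (log2 +0.25, adjusted p = 0.992) and erythroid (log2 +0.05, adjusted p = 0.885). The last was driver and pathway (log2 +0.07, adjusted p = 0.789). The mean differed in sign from the median for mature oligodendrocyte (-0.20) and for hypoxia and glycolysis (+0.03). Leaving out 1 animal gave calls for interferon response (without S93F2, adjusted p = 0.000128), cytosolic ribosome (without S93B3 or S93F2, adjusted p = 0.00294 and 0.0235) and mature oligodendrocyte (without S93F2, adjusted p = 0.0243). Camera pointed against the median for mature neuron, migration and adhesion, ependymal and erythroid. Tubb3, a tubulin of young neurons, was at 308.4 ± 255.1 against 164.1 ± 91.1 CPM (log2 +0.79, SE 0.21, adjusted p = 0.670, higher in 8 of 9 animals). Gap43, a growth cone protein, was at 839 ± 350.4 against 549.6 ± 313.8 CPM (log2 +0.71, SE 0.17, adjusted p = 0.670, higher in 9 of 9). Abundant members of these lists gave log2 values of +0.24 (Cnp), +0.03 (Olig1), −0.42 (Snap25), +0.03 (Irgm1), −0.15 (Eno1), +0.20 (Sparc), −0.16 (Gria2), −0.07 (Rplp0), +0.04 (mt-Cytb), +0.97 (Lck), +0.25 (Tppp3), −1.37 (Hbb-bs), −0.09 (Ccnd1) and −0.11 (Cdk4), none past the test. Adjusted over the list alone, 2 mature oligodendrocyte genes and 1 migration gene were higher.

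No single gene passed edgeR's test for core against margin over all models (0 of 19562 genes, smallest adjusted p = 0.115), while 1310 genes had an unadjusted p below 0.05 (663 higher in core, 647 lower). DESeq2 called 0.956% of the genes (0.583% higher, 0.373% lower), and limma on mean log values called 0. Without S93B3, edgeR called 1 gene. Genes per cell at equal depth were 2770.1 in core and 2677 in margin (higher in 6 of 9 animals, SD of the difference 310.3, exact sign-flip p = 0.457).

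In the EGFR model, genes of cell division were lower in core than in margin. In the G2/M list, 19 of 20 genes were lower adjusted over the list alone and 0 over all genes (median log2 −2.14, adjusted p = 1.42e-24, adjusted p = 0.319 with an estimated correlation). Cdc20 was at 79.4 ± 67.9 against 270.3 ± 97.5 CPM in core and margin (log2 −2.08, SE 0.44, adjusted p = 0.258), and Ccnb1 gave log2 −2.60, SE 0.76, adjusted p = 0.355. In the G1/S list, 13 of 20 were lower adjusted over the list alone and 0 over all genes (median log2 −1.01, adjusted p = 1.36e-16, adjusted p = 0.107 with an estimated correlation). Mcm6 was at 161.9 ± 44.6 against 330.4 ± 41.5 CPM (log2 −1.06, SE 0.22, adjusted p = 0.258) and Pcna gave log2 −0.47. Of 26 cytosolic ribosome genes, 22 were lower adjusted over the list alone and 0 over all genes (median log2 −0.42, adjusted p = 1.32e-17, adjusted p = 0.319 with an estimated correlation). Rplp0 gave log2 −0.63 and Rpl4 log2 −0.58. EGFR core cells also held fewer detected genes at equal depth than margin cells (-202 ± 100.8, lower in 3 of 3 animals).

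All 18 MHC antigen presentation genes lay higher in the EGFR core (median log2 +0.72, adjusted p = 3.12e-06, adjusted p = 0.485 with an estimated correlation), with B2m at log2 +0.72 and H2-D1 at log2 +0.53. The oligodendrocyte precursor list was higher (median log2 +0.33, adjusted p = 0.00103, adjusted p = 0.400 with an estimated correlation), with the lineage factor Olig1 at log2 +0.35. The mature oligodendrocyte list was higher (median log2 +0.71, or +0.92 with members at the count floor, adjusted p = 0.000737, adjusted p = 0.337 with an estimated correlation), with the myelin enzyme Cnp at log2 +0.63, SE 0.21, adjusted p = 0.405. The interferon response was higher (median log2 +0.41, adjusted p = 0.00613, adjusted p = 0.778 with an estimated correlation), and so was the microglia and macrophage list (median log2 +1.32, or +1.78 with members at the count floor, adjusted p = 0.0241, adjusted p = 0.319 with an estimated correlation). All 18 cholesterol synthesis genes lay lower (median log2 −0.62, adjusted p = 1.52e-07, adjusted p = 0.337 with an estimated correlation), with Msmo1 at log2 −0.62. EdgeR called 0 of 19562 genes with 1723 at an unadjusted p below 0.05, DESeq2 called 830 and limma 68. Some list calls rested on 1 animal: interferon on S104B2 (adjusted p = 0.985 and reversed without it) and S116B2 (0.237), mature oligodendrocyte on S116B2 (0.0907), and microglia on S104B2, S116B2 and S94F1 (0.0535, 0.0915 and 0.0653).

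In the NF1-PTEN model, immediate-early and stress genes were higher in core, 8 of 23 adjusted over the list alone and 0 over all genes (median log2 +1.05, adjusted p = 5.23e-10, adjusted p = 0.220 with an estimated correlation). Fos was at 1817 ± 471 against 834 ± 422 CPM in core and margin (log2 +1.25, SE 0.35, adjusted p = 0.495), while Hsp90aa1 gave log2 +0.07. Of 26 cytosolic ribosome genes, 6 were higher adjusted over the list alone (median log2 +0.28, adjusted p = 1.01e-08, adjusted p = 0.525 with an estimated correlation), with Rplp0 at log2 +0.45 and Rpl4 at log2 +0.36. Core cells held more detected genes at equal depth (387 ± 331.2, higher in 3 of 3 animals). S111B1 had the largest difference, at 2857 in core against 2089 in margin, with 2301 against 2078 in S93B3 and 2359 against 2189.5 in S93F2. MAPK feedback genes, induced by the growth factor pathway that some of them damp, were higher (median log2 +0.56, adjusted p = 0.00177, adjusted p = 0.319 with an estimated correlation). Endothelial genes were higher (median log2 +4.74, or +3.97 with members at the count floor, adjusted p = 0.0129, adjusted p = 0.256 with an estimated correlation), with Itm2a at log2 +0.44. Driver and pathway genes were higher (median log2 +0.38, or +0.46 with members at the count floor, adjusted p = 0.0250, adjusted p = 0.409 with an estimated correlation), and astrocyte genes lower (median log2 −0.78, adjusted p = 0.0129, adjusted p = 0.525 with an estimated correlation).

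Single genes gave no call by edgeR in NF1-PTEN (0 of 19562, 1467 at an unadjusted p below 0.05), 601 by DESeq2 and 4 by limma. EdgeR's count became 2 without S93F2 and 1 without S94F1. The MAPK feedback call ended without S111B1 (adjusted p = 0.204), the astrocyte call without S111B1 or S93B3 (0.795 and 0.0606), and the driver and pathway call without any of the 9 animals (0.0606 to 0.616). The endothelial call ended without S104B2, S105B4, S105B6, S93B3 or S93F2 (adjusted p = 0.0780, 0.0804, 0.0707, 0.359 and 0.152).

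In the PDGFR model, cholesterol synthesis genes were lower in core, 10 of 18 adjusted over the list alone and 0 over all genes (median log2 −0.74, adjusted p = 1.24e-22, adjusted p = 0.220 with an estimated correlation). Msmo1 was at 127.3 ± 27.7 against 248.2 ± 73.6 CPM in core and margin (log2 −0.95, SE 0.29) and Hmgcs1 at 102.8 ± 45.5 against 223.02 ± 35.7 CPM (log2 −1.20, SE 0.34), neither past the test over all genes. The astrocyte list was lower (median log2 −0.78, adjusted p = 0.00270, adjusted p = 0.614 with an estimated correlation). The G1/S list was lower (median log2 −0.28, adjusted p = 0.000925, adjusted p = 0.614 with an estimated correlation), with Mcm6 at log2 −0.40. The immediate-early and stress list was higher (median log2 +0.38, adjusted p = 0.0283, adjusted p = 0.664 with an estimated correlation), with Fos at log2 +0.54. The microglia and macrophage list was higher (median log2 +1.05, adjusted p = 0.00149, adjusted p = 0.556 with an estimated correlation), with Hexb at log2 +0.40. PDGFR core cells held more detected genes at equal depth (93.7 ± 75.2, higher in 3 of 3 animals). EdgeR called 0 of 19562 genes with 428 at an unadjusted p below 0.05, DESeq2 called 68 (13 higher, 55 lower) and limma 81 (79 higher, 2 lower). The astrocyte and G1/S calls ended without S105B4 (adjusted p = 0.373 and 0.157), the immediate-early call without S105B6 or S105M3 (0.480 and 0.0986) and the microglia call without S105B6 (0.187). With microglia-like cells kept, the microglia list was lower in core (adjusted p = 0.0122) and Hexb gave log2 −0.06.

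The region effect itself was compared between the models. The permutation tests of lists and of genes per cell used for this were not part of the plan. The G1/S list differed, with a mean log2 difference between core and margin of −1.01 ± 0.28 in EGFR, −0.07 ± 0.01 in NF1-PTEN and −0.23 ± 0.19 in PDGFR (exact permutation test over 1680 assignments, p = 0.00357, adjusted p = 0.0464 over 26 lists). The cytosolic ribosome list differed too, at −0.43 ± 0.22 in EGFR, +0.29 ± 0.19 in NF1-PTEN and 0.00 ± 0.05 in PDGFR (exact p = 0.00357, adjusted p = 0.0464). For both lists this is the smallest p that the permutation test can give. Genes per cell at equal depth moved down in EGFR and up in the other two models (exact p = 0.00714, adjusted p = 0.0214 over 3 tests of this measure). The immediate-early list gave 0.27 ± 0.11, 1.35 ± 0.56 and 0.57 ± 0.35 (exact p = 0.0321, adjusted p = 0.167). The driver list (exact p = 0.0214) and the endothelial list (exact p = 0.0286) also failed the correction (adjusted p = 0.167 each). No gene passed edgeR's test of the difference (0 of 19562, 1206 at an unadjusted p below 0.05), whereas DESeq2 called 1.42% of the genes and limma 13 genes.

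Clustering of all 2977 cells gave 19 clusters, of which 6 took the name of a cell class by their leading genes and 13, with 77.5% of the cells, stayed unnamed. A cluster led by the replication genes Cdc6, Mcm3 and Ung and one led by the MHC genes Cd74, Ciita and H2-Aa stayed unnamed, since the G1/S and MHC lists were not among the marker lists. Cells in G2/M clusters made up 6.51% of EGFR core cells and 19.1% of EGFR margin cells, a difference of −12.6 ± 2.73 points. The share was lower in core in 3 of 3 EGFR animals: 5.38% against 19.3% in S104B2, 11.3% against 25.9% in S116B2 and 2.82% against 12.3% in S94F1. The difference was 3.04 ± 15.5 points in NF1-PTEN and −1.91 ± 7.07 points in PDGFR (exact permutation test between models, p = 0.229, adjusted p = 0.229 over 4 classes). The same test gave p = 0.05 without subtracting animal means (adjusted p = 0.110), 0.0536 at resolution 0.5 (adjusted p = 0.100), 0.261 at resolution 2, 0.396 with the stricter cell filter and 0.139 without genes called between models. Over the 9 animals the share was 14.4 ± 8.33% in core and 18.2 ± 6.16% in margin (exact two-sided sign-flip p = 0.336, adjusted p = 0.448 over 4 classes). Within a model, 3 animals cannot give a sign-flip p below 0.25.

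**Figure D4:**
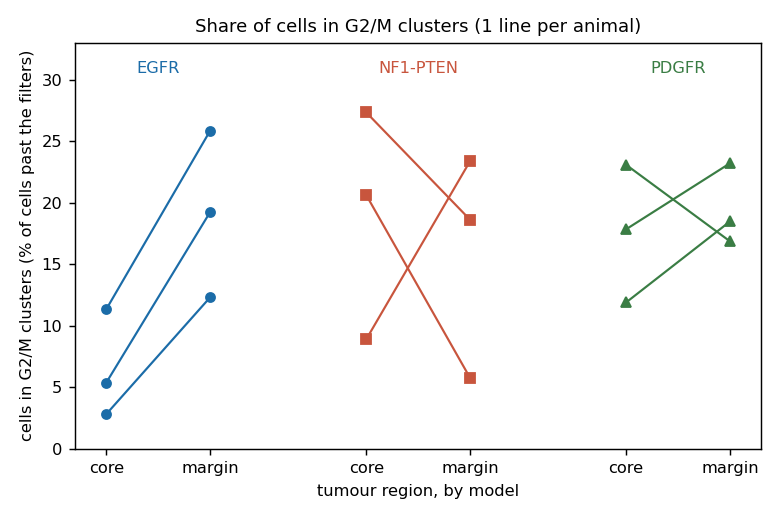
Share of cells in G2/M clusters (vertical axis, percent of the cells past the filters, from 0) in core and margin of each animal, with 1 line per animal and the models side by side. All 3 EGFR animals have the lower share in core (mean 6.51% against 19.1%), and the other models go both ways.

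Astrocyte-like cells made up 0.858 ± 1.40% of core and 4.14 ± 9.49% of margin cells (lower in core in 6 of 9 animals, higher in 0, exact sign-flip p = 0.0312, adjusted p = 0.125). The class held 0 EGFR, 55 NF1-PTEN and 4 PDGFR cells, so the 3 EGFR animals are ties and the PDGFR animals rest on very few cells. With 3 ties this is the smallest p the test can give. NF1-PTEN animal S111B1 carried most of this, with −26.1 points, and without it the mean difference was −0.434 points (exact p = 0.0625, adjusted p = 0.25). Within plates the astrocyte-like share was lower in core on 10, higher on 3 and equal on 20 of 33 plates. Oligodendrocyte-like cells were at 3.67% in core and 3.86% in margin (adjusted p = 0.844). Their difference was 2.79 ± 2.32 points in EGFR (higher in 3 of 3 animals) and −2.64 ± 3.63 points in NF1-PTEN (higher in 0 of 3, exact permutation p between models = 0.0786, adjusted p = 0.157, and exact p = 0.0321, adjusted p = 0.129 with the stricter cell filter). The class pools 2 clusters: one led by Bmp4 and Enpp6, with 45 EGFR, 41 NF1-PTEN and 5 PDGFR cells, and one led by Ermn, Mal, Mobp and Mog, with 0, 9 and 13. Microglia-like cells were at 0.322% and 0.636% (adjusted p = 0.281). Between EGFR, NF1-PTEN and PDGFR, clustering on genes not called between them gave astrocyte-like shares of 0%, 7.74 ± 9.22% and 1.10 ± 1.19% (exact permutation p = 0.0393, adjusted p = 0.136). Clustering on all variable genes gave 0%, 6.94% and 0.365% (adjusted p = 0.0143). The G2/M shares (12.7%, 17.3% and 18.6%, adjusted p = 0.429) and the oligodendrocyte-like shares (4.41%, 5.29% and 1.65%, adjusted p = 0.529) did not pass. Clustering on genes not called between models took PDGFR from the lowest to the highest oligodendrocyte-like share (4.59%, 5.20% and 11.97%, adjusted p = 0.210) and its core minus margin difference to +7.59 ± 8.29 points. The microglia-like shares did not pass either (0.0894%, 0.606% and 0.733%, adjusted p = 0.136).

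Gbp4, Tgtp1, Trp53 and Gdpd3 were higher in EGFR than in NF1-PTEN tumours, and Sparc and Fbln2 were lower. The guanylate-binding protein Gbp4 (chromosome 5, 105115767 to 105139586) averaged 664 ± 870.0 CPM against 0.0738 CPM (log2 +13.69, SE 2.03, adjusted p = 0.0237), and the GTPase Tgtp1 2214 ± 3109.8 against 10.4 ± 0.204 CPM (log2 +7.73, SE 1.36, adjusted p = 0.0485). The tumour suppressor Trp53 (ENSMUSG00000059552.13, chromosome 11, 69580359 to 69591873) was at 215.1 ± 47.99 against 16.9 ± 8.61 CPM (log2 +3.67, SE 0.44, adjusted p = 0.0103). Gdpd3 (ENSMUSG00000030703.8, chromosome 7, 126766334 to 126775649), a lysophospholipase D, was at 51.1 ± 11.4 CPM against 0 in NF1-PTEN, at least 6274-fold higher (3 counts over the group, adjusted p = 0.00213). BC023719 was at 31.1 ± 9.35 against 0.432 ± 0.141 CPM (log2 +6.16, SE 0.87, adjusted p = 0.0205). Sparc, a matrix glycoprotein, was at 86.5 ± 10.2 against 371.5 ± 185.2 CPM (log2 −2.10, SE 0.36, adjusted p = 0.0462), and the matrix protein Fbln2 gave log2 −8.52, SE 1.49, adjusted p = 0.0485. Art3 gave log2 −9.77, SE 1.68, adjusted p = 0.0448, and Crym, a thyroid hormone-binding protein, log2 −9.34, SE 1.47, adjusted p = 0.0322. Art3 and Crym are among the 50 leading genes of an unnamed cluster of 29 cells led by Postn and Col5a2. Those cells entered the sums, and how much of the difference they carry was not tested. Gpr37, a receptor of oligodendrocytes, stood at 0.0042 CPM against 24.04 CPM (adjusted p = 0.0135). It is among the 50 leading genes of the oligodendrocyte-like cluster that holds 0 EGFR and 9 NF1-PTEN cells, and how much of the difference those cells carry was not tested. The lipid droplet protein Plin3 stood at 0.0063 CPM against 7.84 CPM (adjusted p = 0.0237). In all, 0.552% of 19563 genes passed edgeR's test (44 higher in EGFR, 64 lower), with 2713 at an unadjusted p below 0.05. With an animal left out, only 3 to 7 of these 11 named genes kept their call.

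List calls between models, here and below, were not repeated with an animal left out or over other splits, so the weight of single animals is not known. Of 18 MHC antigen presentation genes, 12 were higher in EGFR than in NF1-PTEN adjusted over the list alone and 0 over all genes (median log2 +2.36, adjusted p = 8.47e-11, adjusted p = 0.458 with an estimated correlation). H2-D1 was at 7591 ± 6584 against 1147 ± 616 CPM (log2 +2.73, SE 0.67, adjusted p = 0.127) and B2m gave log2 +1.12. Of 32 interferon response genes, 11 were higher adjusted over the list alone (median log2 +1.36, adjusted p = 1.58e-05, adjusted p = 0.658 with an estimated correlation). The GTPases Irgm1 and Igtp gave log2 +2.65, SE 0.60, adjusted p = 0.106 and log2 +3.89, SE 0.79, adjusted p = 0.0793. Oligodendrocyte precursor genes were higher (median log2 +0.66, adjusted p = 0.00101, adjusted p = 0.658 with an estimated correlation), as were cholesterol synthesis genes (median log2 +0.19, adjusted p = 0.0224, adjusted p = 0.658 with an estimated correlation). Astrocyte genes were lower, 8 adjusted over the list alone and 1 over all genes (median log2 −1.39, adjusted p = 2.59e-06, adjusted p = 0.458 with an estimated correlation), while Cst3 gave log2 −1.29 and Aldoc log2 +0.44. Mature oligodendrocyte genes were lower (median log2 −1.79, adjusted p = 1.58e-05, adjusted p = 0.593 with an estimated correlation), as were extracellular matrix genes (median log2 −2.20, or −2.30 with members at the count floor, adjusted p = 1.79e-05, adjusted p = 0.458 with an estimated correlation). Immediate-early genes were lower (median log2 −0.69, adjusted p = 0.000403, adjusted p = 0.458 with an estimated correlation), as were endothelial genes (median log2 −5.30, or −4.75 with members at the count floor, adjusted p = 0.00674, adjusted p = 0.458 with an estimated correlation). DESeq2 called 1257 genes, which held all of edgeR's, and limma 0.690% of the genes, which held 41. The balance of directions turned under limma (0.521% higher in EGFR, 0.169% lower, against 0.225% and 0.327% by edgeR). It also turned in edgeR without S104B2, S105B4, S105B6, S105M3, S111B1 or S94F1 (without S94F1 0.235% and 0.148%). Leaving out an animal lowered edgeR's count to 42 (S104B2), 48 (S105B4), 51 (S105B6), 60 (S105M3), 65 (S116B2) or 69 (S111B1).

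EGFR and PDGFR tumours differed in 601 of 19563 genes by edgeR (1.70% of the genes higher in EGFR, 1.38% lower, 4131 at an unadjusted p below 0.05). Of 16 oligodendrocyte precursor genes, 15 were higher in EGFR adjusted over the list alone and 9 over all genes (median log2 +2.33, adjusted p = 5.28e-20, adjusted p = 0.328 with an estimated correlation). Olig1 stood at 3427 ± 387 against 916 ± 159.2 CPM (log2 +1.90, SE 0.39, adjusted p = 0.0368), and the receptor phosphatase Ptprz1 gave log2 +1.08, SE 0.26, adjusted p = 0.0596. In the glutamate synapse list, 8 genes were higher and 1 lower adjusted over the list alone, 5 over all genes (median log2 +0.62, adjusted p = 0.000525, adjusted p = 0.400 with an estimated correlation), and the mean log2 of −0.16 differed in sign from the median. The AMPA receptor subunit Gria2 gave log2 +1.53, SE 0.32, adjusted p = 0.0400, and the presynaptic protein Nrxn1 was at 103.05 ± 21.2 against 24.6 ± 5.45 CPM (log2 +2.07, SE 0.35, adjusted p = 0.0201). Of the reactive injury genes, 9 were lower and 1 higher adjusted over the list alone, 4 over all genes (median log2 −2.88, adjusted p = 1.46e-06, adjusted p = 0.400 with an estimated correlation). Lgals1 was at 14.3 ± 10.5 against 1433 ± 524 CPM (log2 −6.64, SE 0.95, adjusted p = 0.00948) and Vim gave log2 −1.30, SE 0.34, adjusted p = 0.0787. Of the extracellular matrix genes, 9 were lower adjusted over the list alone and 3 over all genes (median log2 −3.54, adjusted p = 2.41e-06, adjusted p = 0.400 with an estimated correlation). Sparc gave log2 −1.75, SE 0.36, adjusted p = 0.0377 and Tnc, another matrix glycoprotein, log2 −3.42, SE 0.73, adjusted p = 0.0418.

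Of 26 cytosolic ribosome genes, 16 were lower in EGFR than in PDGFR adjusted over the list alone and 1 over all genes (median log2 −0.89, adjusted p = 1.09e-08, adjusted p = 0.400 with an estimated correlation), with Rplp0 at log2 −1.38. PDGFR cells also held more detected genes. Mature oligodendrocyte genes were lower in EGFR (median log2 −1.42, adjusted p = 0.000368, adjusted p = 0.474 with an estimated correlation), as were interferon response genes (median log2 −0.54, adjusted p = 0.00673, adjusted p = 0.719 with an estimated correlation). Hypoxia and glycolysis genes were lower (median log2 −0.54, adjusted p = 0.0199, adjusted p = 0.400 with an estimated correlation), as were genes of the mitochondrial genome (median log2 −0.51, adjusted p = 0.00892, adjusted p = 0.400 with an estimated correlation). Endothelial genes were lower (median log2 −2.41, adjusted p = 0.0105, adjusted p = 0.328 with an estimated correlation) and cholesterol synthesis genes higher (median log2 +0.61, adjusted p = 0.000637, adjusted p = 0.400 with an estimated correlation). The homeobox gene Meox1 gave log2 +8.82, SE 1.45, adjusted p = 0.0172, and Aldh1a1, which makes retinoic acid, log2 +7.98, SE 1.502, adjusted p = 0.0277. Gdpd3 gave log2 +7.94, SE 0.65, adjusted p = 0.00361, Asic4 log2 +7.81, SE 1.40, adjusted p = 0.0237 and Rnf43, which removes Wnt receptors, log2 +6.42, SE 1.14, adjusted p = 0.0225. The EGF receptor ligand Areg stood at 0.0105 against 122.6 ± 118.6 CPM (log2 −13.05, SE 2.12, adjusted p = 0.0164). The oligodendrocyte genes Ermn and Aspa had 0 counts in EGFR and were at least 1892-fold and 1377-fold lower (3 counts over the group, adjusted p = 0.0275 and 0.0444). Both are among the 50 leading genes of the oligodendrocyte-like cluster that holds 0 EGFR and 13 PDGFR cells. Aspa is also among those of the unnamed cluster of 29 cells led by Postn and Col5a2. How much of the difference the cells of these clusters carry was not tested. Plin3 stood at 0.0063 against 54.5 CPM (adjusted p = 0.00669), and the AP-1 factor Fosl1 at 0.0042 against 36.5 CPM (adjusted p = 0.00948).

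For EGFR against PDGFR, DESeq2 called 2619 genes, which held 592 of edgeR's 601. Limma on mean log values called 8117 (470 higher, 7647 lower), which held 463 of them, and moved the median log2 of all genes to −0.20. Cells thinned to equal depth gave 973 calls. Leaving out an animal lowered edgeR's calls from 3.07% of the genes to 0.803% (S105B6), 0.946% (S94F1), 0.981% (S105B4), 0.997% (S105M3) or 1.01% (S104B2).

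NF1-PTEN and PDGFR tumours differed in 0.808% of 19563 genes (94 higher in NF1-PTEN, 64 lower, 2912 at an unadjusted p below 0.05). Of 32 interferon response genes, 13 were lower in NF1-PTEN and 1 higher adjusted over the list alone, 0 over all genes (median log2 −1.74, adjusted p = 1.53e-14, adjusted p = 0.425 with an estimated correlation). Irgm1 gave log2 −2.59, SE 0.60, adjusted p = 0.0923 and Igtp log2 −3.47, SE 0.77, adjusted p = 0.0835. Gbp4 averaged 0.0738 against 1059 ± 578 CPM (log2 −14.37, SE 2.07, adjusted p = 0.0319). The interferon-inducible genes Ifi209 and Slfn2 had 0 counts in NF1-PTEN and were at least 6193-fold and 4439-fold lower (3 counts over the group, adjusted p = 0.0424 and 0.0337). Of 18 MHC antigen presentation genes, 12 were lower adjusted over the list alone and 0 over all genes (median log2 −2.45, adjusted p = 4.15e-13, adjusted p = 0.324 with an estimated correlation), with B2m at log2 −1.75 and H2-D1 at log2 −1.84. Of 16 oligodendrocyte precursor genes, 10 were higher adjusted over the list alone and 3 over all genes (median log2 +1.69, adjusted p = 1.69e-14, adjusted p = 0.324 with an estimated correlation), with Olig1 at log2 +0.82 and Ptprz1 at log2 +0.43. Astrocyte genes were higher (median log2 +1.18, adjusted p = 3.97e-06, adjusted p = 0.324 with an estimated correlation), with Cst3 at log2 +1.02 and Aldoc at log2 +1.02. Rlbp1, a retinaldehyde-binding protein, was at 553 ± 449 against 6.24 ± 4.21 CPM (log2 +6.47, SE 0.87, adjusted p = 0.0303).

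Glutamate synapse genes were higher in NF1-PTEN than in PDGFR (median log2 +0.61, adjusted p = 0.000572, adjusted p = 0.324 with an estimated correlation), with Nrxn1 at log2 +1.78, SE 0.35, adjusted p = 0.0621 and Gria2 at log2 +0.67. Reactive injury genes were lower (median log2 −1.68, adjusted p = 3.35e-06, adjusted p = 0.324 with an estimated correlation), and so were cytosolic ribosome genes (median log2 −0.65, adjusted p = 4.41e-07, adjusted p = 0.573 with an estimated correlation). Meox1 gave log2 +10.11, SE 1.52, adjusted p = 0.0319, Rnf43 log2 +7.02, SE 1.17, adjusted p = 0.0389, Krt1 log2 +6.22, SE 1.02, adjusted p = 0.0370 and Arpp21 log2 +5.96, SE 0.64, adjusted p = 0.0162. Gdpd3 had 0 counts in NF1-PTEN and was at least 28.1-fold lower (3 counts over the group, adjusted p = 0.0319), and AA467197 gave log2 −5.83, SE 1.05, adjusted p = 0.0450. DESeq2 called 1485 genes, which held all of edgeR's. Limma called 7141 (1.40% of the genes higher, 35.1% lower, a balance opposite to edgeR's), which held 74.7% of edgeR's, and again moved the median of all genes to −0.20. Thinned cells gave 437 calls. Leaving out an animal moved edgeR's count to 0 (S104B2 or S105M3), 1 (S105B6), 4 (S105B4), 5 (S93B3), 63 (S93F2), 89 (S111B1) or 100 (S94F1), and from 0.808% to 1.24% of the genes without S116B2 (0.552% higher, 0.685% lower, again opposite).

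Wells labelled empty served as the background. Of 32 such wells, 29 held at most 87 counts and 74 genes (median 0 counts). The other 3 held as many counts as a cell: 384086 on a plate of an NF1-PTEN animal, 412906 on a plate of an EGFR animal and 203910 on a plate of a PDGFR animal.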

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

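Chosen only after the results were seen were the test of Xist counts, the test for EGFR cells among the wells, the test of the transgenes in named clusters and all counts over other splits of the animals.

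Among 30 groups of 9 animals searched for a value far from the others, 3 held one, where chance gives about 1 in 20. The T and NK cell list in S105B4 had a core minus margin difference of −2.63, with the nearest other animal at 0.18. The migration and adhesion list in S93B3 had −1.07, with the nearest at −0.26. The share of astrocyte-like cells in S111B1 had −26.1 points, with the nearest at −1.83. The difference between core and margin itself differed between the models for the G1/S list (exact permutation test, adjusted p = 0.0464), for the cytosolic ribosome list (exact, adjusted p = 0.0464) and for genes per cell at equal depth (exact p = 0.00714, adjusted p = 0.0214). These permutation tests were not part of the plan. Among wells labelled empty, which no comparison used, 3 held the counts of a cell. The well on a plate of an NF1-PTEN animal held 384086 counts, with 684 of iCRE and 520 of tdTomato. That on a plate of an EGFR animal held 412906 counts, with 3595 of Egfrviii and 423 of tdTomato. That on a plate of a PDGFR animal held 203910 counts, with 682 of Pdgfra_D842V and 9 of iCRE.

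Egfrviii, the transgene of the EGFR model, also had 400.19 counts in plate P2932 of PDGFR animal S105M3, spread over 86 of 91 wells. Cells of an EGFR tumour among the wells are argued against, since the highest well held 15 counts and the median well 4, where the median EGFR cell held 2133. Reads assigned from EGFR plate P2930 would need 0.0581% of the Egfrviii there, yet P2931, which lies between them, held 0 counts, as did P2776, whose well numbers follow on from EGFR plates P2774 and P2775, and the well numbers of P2930 put it in another set of 384 than P2931 and P2932. The 1 gene with at least 100 CPM in P2930 and none in the animal's 3 other plates, Aldh1a1, gave 2 counts against 5.59 foretold (0.358 times), and Xist 1.28 times (30.6 counts), but P2931 held 12 Xist counts, so neither test decides. The labels do not say which plates shared a lane, no further explanation was tested, and the source of these counts stays open.

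By camera with its preset correlation the G2/M and cholesterol synthesis lists were lower in core and the immediate-early and stress list higher, but none passed with an estimated correlation (adjusted p = 0.348, 0.180 and 0.180), and the G2/M list was lower in 6 of 9 animals only (exact sign-flip test, adjusted p = 0.305) with medians of −2.14 in EGFR, +0.02 in NF1-PTEN and −0.33 in PDGFR. With every cell thinned to 20000 counts the G2/M median went from −0.71 to −0.73 (1.03 times) and the cholesterol median stayed at −0.51 (1.004 times). The medians thus did not rest on deeper cells weighing more in the sums. Drawing counts at random keeps the expected share of each gene within a cell, so thinning cannot decide on other effects of depth. RNA of microglia or macrophages in core cells is argued against for the immediate-early list. Its median, here of the mean differences over the 9 animals, was 0.50 both with and without cells holding a count of C1qa, C1qb or C1qc (0.995 times, 0% to 5.43% of cells). Over exchanges of core and margin within animals, 3 of 30 splits moved as many lists as the real one (9 lists, highest other 9), so chance is not excluded for the number of lists. Each exchanged split moved at least 2 lists. Where the cells lay in the tumour stays open as an explanation, as do differences in handling between the regions.

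Clusters named astrocyte-like or oligodendrocyte-like could be normal brain cells caught in the sort. For the oligodendrocyte-like cells of EGFR this is argued against as the source of most, as 45 of 45 (100%, 95% interval 92.1% to 100%) held at least 10 counts of Egfrviii, with a median of 1516, although the 1 microglia-like EGFR cell held 1772. Of those of PDGFR, 14 of 18 (77.8%, 52.4% to 93.6%) held at least 10 counts of Pdgfra_D842V, against 1 of 8 microglia-like PDGFR cells (12.5%, 0.316% to 52.7%), but the intervals overlap and reads of Pdgfra can be assigned to this sequence. Pdgfra_D842V stood at 300.6 CPM in NF1-PTEN animal S111B1, above Pdgfra itself there (219.002 CPM), and at 14.9 to 55.8 CPM in the other EGFR and NF1-PTEN animals. The source of the level in S111B1 was not tested. In NF1-PTEN the score was tdTomato, held by 45 of 50 oligodendrocyte-like cells, and 55 of the 59 astrocyte-like cells were NF1-PTEN cells; over all 59, 74.6% held at least 10 counts of the transgene of their model. The sources used here do not give whether normal cells of the NF1-PTEN animals can express tdTomato, so normal cells stay open for the astrocyte-like cells and for the oligodendrocyte-like cells of PDGFR and NF1-PTEN.

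Other splits of the animals were counted for each comparison. Where edgeR called 0 genes every split reaches that count, so it says nothing about chance: 30 of 30 splits for core against margin over all models, 50 of 50 for the difference between models in the effect of region, and 4 of 4 within each of EGFR, NF1-PTEN and PDGFR (highest other 0 in each). The number of genes at an unadjusted p below 0.05 over all models was reached by 1 of 30 splits, the real one (1310 genes, highest other 1100). That share is under 0.05 and the smallest that 30 splits can give. As the count was chosen after the results were seen, chance is not excluded for that number. For the difference between models in the effect of region that number was reached by 1 of 50 splits, again the real one (1206 genes, highest other 989). The number of splits drawn here was raised after smaller draws had been seen, at first to bring a share under 0.05 within reach. Chance is therefore not excluded for this number either. Between models, 10 splits are too few for a share under 0.05, and 1 of 10 gave as many in each: for EGFR against NF1-PTEN the real split called 0.552% of the genes and the highest other 1 gene, for EGFR against PDGFR 601 genes and 0, and for NF1-PTEN against PDGFR 0.808% of the genes and 0.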

How the results depend on the processing

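Chosen after seeing the data were genes with at least 10 CPM, leaving out S111B1 and S105M3 together, the sign-flip test of lists, clustering without genes called between models, fry for lists between models, the resolution and stricter filter for shares between models, and all tests of whether the share difference between core and margin differs between models. The plan also did not hold the permutation test of lists between models or the tests of genes per cell. Clustering without genes called between core and margin was not run, since edgeR called none. Of 1417 values of 71 named genes between core and margin, 1350 kept their direction and their side of the threshold, 11 gained a call and 56 turned. EdgeR had called none of these genes, so no call could be lost and keeping the side meant staying uncalled. Of 1292 values of 68 named genes between models, 991 kept direction and side, 39 gained a call, 16 turned and the others lost the call. Of 724 list values for 73 lists and comparisons, 521 kept both, 4 gained a call, 32 turned and the others lost the call. For lists between models these values come only from the estimated correlation and fry, with no animal left out. By camera with its preset correlation the G1/S, G2/M, cholesterol, immediate-early and MHC lists over all models kept their call in 9 of 9 fits with an animal left out (highest adjusted p = 2.24e-06, 1.70e-08, 4.45e-14, 5.94e-05 and 0.000705). That setting also called 2 to 9 lists in every exchanged split drawn, so kept calls do not establish a difference. None of these lists passed with an estimated correlation or by the sign-flip test over animals. Of 11 named genes called for EGFR against NF1-PTEN, 3 (without S104B2) to 7 (without S93F2) kept the call with an animal left out. Of 17 for EGFR against PDGFR, 3 (without S94F1) to 17 (without S93F2) kept it, and of 10 for NF1-PTEN against PDGFR, 0 (without S104B2, S105B6 or S105M3) to 10 (without S116B2). Without the animal block, the reactive injury and endothelial calls over all models ended (adjusted p = 0.126 and 0.178), and the block changed no other call of a list between core and margin. In percent of the genes tested, where 0.00511% is 1 gene, edgeR called 0 for each comparison of core and margin, 0.552% for EGFR against NF1-PTEN, 3.07% for EGFR against PDGFR and 0.808% for NF1-PTEN against PDGFR, and camera called 9 lists over all models, 9 in EGFR, 6 in NF1-PTEN, 5 in PDGFR, and 9, 11 and 7 between the models in the same order. The values below stand against these. Whether depth limited what was called was not settled, as thinning every cell to 20000 counts raised the calls between models. The cause of the changes below was not tested, except that leaving out animals or genes leaves fewer to test.

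DESeq2 gave calls of 0.956% (all models), 4.24% (EGFR), 3.07% (NF1-PTEN), 0.348% (PDGFR), 1.42% (difference of the region effect), 6.43% (EGFR against NF1-PTEN), 13.4% (EGFR against PDGFR), 7.59% (NF1-PTEN against PDGFR), and log2 values of the other sign for Nf1 −0.022 (EGFR against NF1-PTEN). RLE size factors gave log2 values of the other sign for Nf1 −0.022 (EGFR against NF1-PTEN). Leaving out S111B1 and S105M3 together gave calls of 0.102% (EGFR against NF1-PTEN), 0.675% (EGFR against PDGFR), 0% (NF1-PTEN against PDGFR), 5 called lists for all models, lists of the other direction at adjusted p interferon response 0.717, migration and adhesion 0.849, driver and pathway 0.760 (all models), and log2 values of the other sign for Pdgfra −0.13, Egfr +0.31, Aldoc +0.10, Irgm1 −0.039, Sparc −0.026 (all models), Pdgfra −0.23, Nf1 −0.39 (NF1-PTEN). Without subtracting animal means the clustering gave astrocyte-like share between models adjusted p 0.0571. Cells thinned to 20000 counts gave calls of 0.0307% (EGFR), 0.00511% (NF1-PTEN), 0.00511% (difference of the region effect), 4.97% (EGFR against PDGFR), 2.23% (NF1-PTEN against PDGFR), and log2 values of the other sign for Hsp90aa1 +0.0074 (all models), Egfr −0.52, Nf1 −0.14 (NF1-PTEN), Nf1 −0.27 (EGFR against NF1-PTEN). Clustering without genes called between models gave oligodendrocyte-like share, core minus margin +2.99 points, astrocyte-like share between models adjusted p 0.136. With an estimated correlation camera gave 0 called lists for all models, EGFR, NF1-PTEN, PDGFR, EGFR against NF1-PTEN, EGFR against PDGFR, NF1-PTEN against PDGFR. The alternative test fry gave 0 called lists for all models, PDGFR, EGFR against NF1-PTEN, NF1-PTEN against PDGFR, 1 for EGFR, 2 for NF1-PTEN, and lists of the other direction at adjusted p hypoxia and glycolysis 0.903, ependymal 0.952 (all models). Genes with at least 10 CPM gave calls of 0.00511% (all models), 1.54% (NF1-PTEN against PDGFR), and log2 values of the other sign for Nf1 −0.055 (EGFR against NF1-PTEN). With immune- and vascular-like cells kept there were lists of the other direction at adjusted p microglia and macrophage 0.166 (all models), microglia and macrophage 0.0122 (PDGFR), and log2 values of the other sign for Hexb −0.058 (PDGFR), Nf1 −0.011 (EGFR against NF1-PTEN). Limma on mean log values of cells gave calls of 0.348% (EGFR), 0.0204% (NF1-PTEN), 0.414% (PDGFR), 0.0665% (difference of the region effect), 41.5% (EGFR against PDGFR), 36.5% (NF1-PTEN against PDGFR), and log2 values of the other sign for Pten +0.21, Aldoc +0.28, Hsp90aa1 +0.032, Rplp0 +0.053 (all models), Pdgfra −0.24, Pten +0.025 (EGFR), Egfr −0.43, Itm2a −0.0089 (NF1-PTEN), Pdgfra +0.097 (PDGFR), Nf1 −0.10, Cst3 +0.14 (EGFR against NF1-PTEN), Nf1 −0.63 (EGFR against PDGFR), Pdgfra −0.099, Nf1 −0.53, Cst3 −0.37, Aldoc −1.01, Gria2 −0.045 (NF1-PTEN against PDGFR). No filter on low counts gave log2 values of the other sign for Nf1 −0.0022 (EGFR against NF1-PTEN). A fit with no replicate block for the animal gave calls of 0.00511% (NF1-PTEN), lists of the other direction at adjusted p ependymal 0.961 (all models), and log2 values of the other sign for Pten +0.038, Cst3 −0.43, Aldoc +0.075 (all models), Egfr −1.22 (NF1-PTEN). The sign-flip test over animals gave 0 called lists for all models, and lists of the other direction at adjusted p mature oligodendrocyte 0.888, migration and adhesion 1, ependymal 0.888 (all models). The stricter cell filter gave log2 values of the other sign for Aldoc +0.20, Hsp90aa1 +0.012 (all models), and microglia-like share, core minus margin +0.0106 points, astrocyte-like share between models adjusted p 0.5.

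Leaving out each animal in turn, calls as percent of genes ran from 0 (S104B2) to 0.00511 (S93B3) for all models, from 0 (S104B2) to 0.0102 (S93F2) for NF1-PTEN, from 0.215 (S104B2) to 0.419 (S93F2) for EGFR against NF1-PTEN, from 0.803 (S105B6) to 3.98 (S93F2) for EGFR against PDGFR, from 0 (S104B2) to 1.24 (S116B2) for NF1-PTEN against PDGFR. Lists that turned or gained a call ran, in adjusted p (all models): interferon response 0.000128 (S93F2) to 0.9498 (S105M3), hypoxia and glycolysis 0.735 (S94F1) to 0.968 (S105B6), migration and adhesion 0.593 (S93B3) to 0.994 (S116B2), MAPK feedback 0.153 (S105B4) to 0.945 (S111B1), glutamate synapse 0.717 (S105B6) to 0.964 (S105B4), cytosolic ribosome 0.00294 (S93B3) to 0.794 (S94F1), ependymal 0.546 (S116B2) to 0.968 (S105B6), erythroid 0.616 (S116B2) to 0.968 (S105B6), driver and pathway 0.441 (S116B2) to 0.966 (S93F2). Lists that turned or gained a call ran, in adjusted p (EGFR): interferon response 6.21e-10 (S94F1) to 0.985 (S104B2). Genes that turned ran, in log2 (all models): Pdgfra −0.14 (S111B1) to +0.31 (S105B4), Egfr −0.90 (S93B3) to +0.49 (S105B4), Cst3 −0.035 (S105B6) to +0.35 (S111B1), Aldoc −0.28 (S116B2) to +0.082 (S111B1), Olig1 −0.034 (S111B1) to +0.12 (S105M3), Irgm1 −0.13 (S104B2) to +0.21 (S93F2), Hsp90aa1 −0.044 (S93B3) to +0.027 (S105B6), Rplp0 −0.19 (S93B3) to +0.036 (S94F1), Tppp3 −0.22 (S93F2) to +0.54 (S94F1). Genes that turned ran, in log2 (EGFR): Pten −0.29 (S94F1) to +0.030 (S104B2). Genes that turned ran, in log2 (NF1-PTEN): Egfr −1.66 (S93B3) to +3.40 (S111B1), Pdgfra −0.23 (S111B1) to +0.99 (S93F2), Nf1 −0.39 (S111B1) to +0.64 (S93B3), Hsp90aa1 −0.0049 (S93B3) to +0.21 (S93F2). Genes that turned ran, in log2 (PDGFR): Egfr −3.04 (S105M3) to +0.11 (S105B4), Pdgfra −1.01 (S105B6) to +0.33 (S105B4), Nf1 −0.053 (S105B6) to +0.34 (S105B4). Genes that turned ran, in log2 (EGFR against NF1-PTEN): Nf1 −0.27 (S93F2) to +0.35 (S93B3). The oligodendrocyte-like share, core minus margin ran from −0.894 points (S104B2) to +0.633 points (S93B3).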

Other observations

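The tests of the added sequences and of Cdkn2a and Trp53 between core and margin were chosen after their values were seen. The reporter tdTomato was higher in core in 9 of 9 animals (log2 +0.28 ± 0.23, 830 against 688 CPM, exact two-sided sign-flip p = 0.00391, adjusted p = 0.0508 over 13 sequences and genes), which fails the correction. The recombinase iCRE gave +0.53 ± 0.96 (higher in 7 of 9, exact p = 0.109, adjusted p = 0.474). Egfrviii gave −0.01 ± 0.25 in the 3 EGFR animals (8479 against 8562 CPM), and Pdgfra_D842V +0.22 ± 0.33 in the 3 PDGFR animals (1277 against 1097 CPM). Cdkn2a, which encodes the cell-cycle inhibitor p16, gave +0.67 ± 0.72 (10.9 against 4.93 CPM, higher in 8 of 9 animals, exact p = 0.0273, adjusted p = 0.178). Trp53 gave −0.04 ± 0.26 (higher in 4 of 9, exact p = 0.637, adjusted p = 0.828). By model, Cdkn2a averaged 0.650 ± 0.226 CPM in EGFR, 5.27 ± 2.29 CPM in NF1-PTEN and 18.2 ± 8.25 CPM in PDGFR. Trp53 averaged 211.2 ± 37.5 CPM, 18.1 ± 9.28 CPM and 17.2 ± 3.39 CPM in the same order. All levels here are on plain library totals, without TMM scaling.

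Counts of Xist lay above those of the Y-linked genes in 2 of 9 animals, 1 in EGFR and 1 in NF1-PTEN, and the reverse held in the other 7, which include all 3 PDGFR animals.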
